A study of Mus musculus with 15 samples.

How the data were processed

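Total RNA of mouse submandibular glands was sequenced in 15 libraries, 3 in each of the groups NT, IR, IR+GFP, IR+Gli1 and IR+Shh. Per the labels, irradiated glands were taken 7 days after irradiation, RNA was purified with RNeasy columns, and libraries were made with a TruSeq RNA kit from 1 ug of total RNA and read on an Illumina HiSeq instrument. The deposited tables hold raw counts of reads per Ensembl gene. According to the processing notes, the authors used Bowtie 0.12.2, TopHat2 2.0.13, HTSeq 0.10.0 and DESeq2 with the builds mm10 and GRCm38; the strand mode, the annotation release and the DESeq2 version are not given. The last lines of each table, which count reads given to no gene, show that reads with several alignments were not counted. Gene symbols, types and coordinates were taken from GENCODE vM21 (GRCm38), which gave a symbol for 96.0% of the genes.

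In each group, a pair of libraries differed by less than independent sampling of reads gives. The chi-square between libraries was taken over genes with at least 20 reads in both together. In the 5 pairs the smaller library was 0.591 to 0.683 of the depth of the larger, and had more reads than the larger in 1 to 5 genes, against 1477 to 9279 genes in other pairs. Such libraries are not independent, and each pair was combined by the rounded mean of its counts. This left 2 samples per group and 10 in all; the plan made before the data were examined had foreseen a fit of 15 separate libraries, which became an alternative when the pairs were combined. Library numbers were not taken to pair the libraries between groups: of 30 same-numbered pairs, 3 deviated from their group means with r over 0.1, and 6 of 15 libraries correlated best with their own number. The 3 were those of IR+GFP with IR+Gli1 (r 0.535 to 0.598). As libraries 1 and 2 of both groups are near-identical and values were taken from group means, these 3 are not independent of each other. For the same reason IR+GFP 1 and IR+Gli1 2, of different numbers, had r = 0.579, which cannot speak for or against pairing. This pairing of IR+GFP with IR+Gli1 was also fitted, with a term for IR+GFP 3 and IR+Gli1 3.

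Genes were filtered with filterByExpr, which kept 14300, and scaled with TMM. All 10 samples were fitted together in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, no covariates and robust quasi-likelihood tests, which left 5 residual degrees of freedom; the common biological coefficient of variation was 0.191. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The prior count was 2 for log2 values. The 5 comparisons were IR with NT, IR+GFP with IR, IR+Gli1 and IR+Shh each with IR+GFP, and IR+Shh with IR+Gli1. Lower bounds of ratios used a floor of 3 reads over the group, and counting intervals are 95% intervals. Both were taken from counts after pairs were averaged and rounded, so they only approximate the counting error of the sequenced reads.

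Before the data were examined, 34 gene lists (644 symbols, 634 of them unique) were written. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with a minimum of 4 tested genes. Genes raised or lowered in IR against NT were tested as sets in the gene transfer comparisons, adjusted over 4 tests. The fold changes of IR+Gli1 and IR+Shh were correlated across genes and set beside 100 simulations of unchanged groups against the same controls.

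Named genes followed a rule written before the data were examined. Gli1 and Shh came first. In each comparison the rule took the 8 largest rises and the 8 largest falls among genes that passed, with a mean of at least 2 CPM in the higher group and no overlap between groups, passing over unnamed gene models. It then took up to 4 members of each list that passed or held a passing gene, by smallest adjusted p, up to 2 members of other lists as values, and the 3 genes of smallest p where fewer than 3 passed. Some genes that the rule named are not reported here.

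Alternative settings were DESeq2 size factors, upper-quartile scaling, no low-count filter, a filter at 1 CPM in 3 libraries, the replicate number as a block in a fit of the 15 separate libraries, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, an estimated correlation between list genes, fry, sets of 200 genes, and leaving out each sample in turn. Others were chosen after seeing the data: setting the planned fit of 15 libraries beside the combined one, the deeper library of each pair, a term for IR+GFP 3 and IR+Gli1 3, leaving out these libraries, protein-coding genes alone, total-count scaling, IR and IR+GFP together as control, and the fit of IR+Gli1 and IR+GFP alone with that term.

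The analysis was tested on simulated data at the depth and spread of these samples. With 2 samples per group it recovered 47.5% to 51.0% of genes changed 2-fold and 75.0% to 79.2% of genes changed 4-fold, and 4.44% to 9.91% of calls were false. Of 136 random lists per comparison 0 passed, and 4 of 4 raised lists passed. Genes were simulated independently of each other, so the simulations could not show false list calls that come from correlation between genes. At the depths given in the report, 0 reads of a gene allow up to 0.0731 to 0.165 CPM in a single library.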

Results

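RNA of the submandibular salivary gland of adult male C57BL/6 mice was sequenced in 15 libraries, 3 in each of 5 groups. The groups were untreated glands (NT), glands 7 days after local irradiation (IR), and irradiated glands given the gene for green fluorescent protein (IR+GFP), Gli1 (IR+Gli1) or Shh (IR+Shh). Shh is the secreted ligand of the Hedgehog pathway, and Gli1 is a transcription factor that the pathway induces and that acts at its end. Gene reads per library ranged from 18205941 to 41064723. In each group, a pair of libraries differed by less than sampling noise: the mean chi-square per gene was 0.215 to 0.337 in these 5 pairs, and 22.0 to 223 in the 10 other pairs within groups. The libraries of each such pair (NT 2 and 3, IR 1 and 2, IR+GFP 1 and 2, IR+Gli1 1 and 2, IR+Shh 1 and 3) were combined into 1 sample, which left n = 2 samples per group. Levels are read counts relative to library size (CPM, TMM-scaled) with their standard deviation, apart from summed sublingual gland genes, limits for 0 reads and values said to be per total gene reads, which carry no TMM factor, and log2 fold changes carry the standard error of the fit. No label says whether libraries came from separate animals, so the p-values measure only the spread between these samples. Intervals and lower bounds of ratios cover counting error only. They, and read numbers given for a group, use the rounded mean of each pair, where a lone read can be lost.

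Reads of Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974, GRCm38) were few in 4 of the 5 groups and more frequent in IR+Shh. The mean was 0.560 ± 0.066 CPM in NT, 0.657 ± 0.065 in IR, 0.661 ± 0.151 in IR+GFP and 0.606 ± 0.093 in the group labelled IR+Gli1 (SD, n = 2 each). It was 3.46 ± 1.10 CPM in IR+Shh (SD, n = 2). Per total gene reads, Gli1 was at 0.878 to 0.962 CPM in the 3 libraries of IR+Gli1, above the 0.424 to 0.747 CPM of the NT, IR and IR+GFP libraries, so the order of these groups depends on the scaling. Shh (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256) had 0 reads in all 15 libraries, which allows up to 0.0731 to 0.165 CPM, depending on the library. The species and sequence of the transferred genes are not given in the labels, so these reads do not show whether a transferred gene was present.

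**Figure D1:**
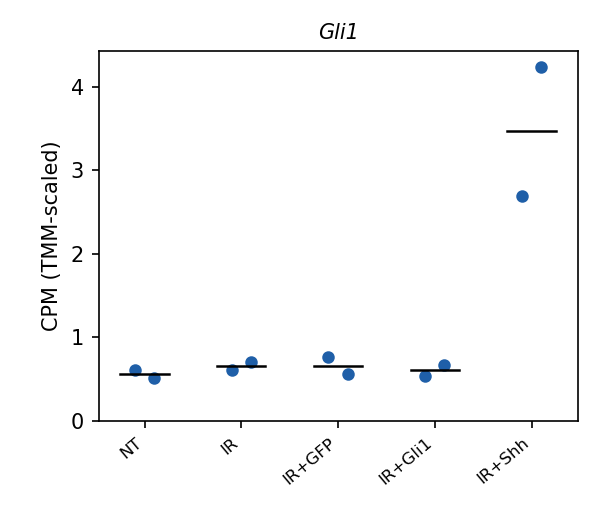
Gli1 level in CPM (vertical axis) in the 10 samples, by group (horizontal axis). Points are samples and lines are group means; the IR+Shh mean is 3.46 CPM and the other 4 means lie between 0.560 and 0.661 CPM.

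The first comparison, IR against NT, asked what differed in the gland 7 days after irradiation. Targets of p53, the transcription factor activated by DNA damage, rose. Cdkn1a, which encodes the cell cycle inhibitor p21, was 17.8-fold higher, at 23.2 ± 1.22 CPM in IR and 1.28 ± 0.156 CPM in NT (SD, n = 2; log2 fold change 4.16 ± 0.39, adjusted p = 0.00618). Eda2r, a receptor of the tumour necrosis factor family, rose 8.54-fold (log2 3.09 ± 0.18), Phlda3 4.61-fold (2.21 ± 0.17), Trp53inp1 3.83-fold (1.94 ± 0.14) and Ccng1 2.62-fold (1.39 ± 0.12). Of the 28 measured p53 targets, 13 rose, 0 fell and 15 did not pass, and 20 rose when adjusted over the list alone. The list passed camera with adjusted p = 1.1e-55, and with adjusted p = 0.0119 with an estimated correlation.

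Across all 14300 genes tested, 97 changed in IR, 74 upward and 23 downward. Besides Cdkn1a and Eda2r, the largest rises were those of Psrc1 (log2 4.35 ± 0.54), the secreted stress factor Gdf15 (4.32 ± 0.60), Ddias (3.57 ± 0.46), Ddit4l (2.87 ± 0.48), Inka2 (2.72 ± 0.36) and Tmem44 (2.58 ± 0.23). The largest falls were those of Slc35g2 (-1.93 ± 0.34), the transcription factor Nfil3 (-1.40 ± 0.22), Sqle, an enzyme of cholesterol synthesis (-1.29 ± 0.19), and Creld2 (-1.29 ± 0.21). Ppa1 (-1.14 ± 0.14), Ostc (-0.91 ± 0.12), Gmds (-0.85 ± 0.12) and Pdia3 (-0.81 ± 0.14) followed; Ostc and Pdia3 act on proteins in the endoplasmic reticulum. Xpc was the 1 gene of 33 DNA repair genes that passed (log2 0.70 ± 0.10), and Ascl3 the 1 of 19 duct and ionocyte genes (0.90 ± 0.14).

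Of the 34 gene lists 7 passed camera, against 1 with an estimated correlation and 2 with fry. Circadian clock genes rose as a list (median log2 0.48, adjusted p = 2.62e-06; adjusted p = 0.0349 with fry and adjusted p = 0.144 with an estimated correlation). None of the 17 passed over all genes, while 9 rose and 1 fell when adjusted over the list alone; Per3 had a log2 fold change of 1.13 ± 0.21 and Bhlhe41 of 0.67 ± 0.13. Duct and ionocyte genes (median log2 0.21, adjusted p = 0.0129) and the 6 skeletal muscle genes (1.09, adjusted p = 0.0217) rose as lists; the adjusted p was 0.816 and 0.578 with an estimated correlation. The duct list did not pass without IR 3 (adjusted p = 0.122) or without NT 2 and 3 (0.206), nor the muscle list without NT 1 (0.215). Endoplasmic reticulum stress and secretory genes fell as a list (median log2 -0.33, adjusted p = 8.02e-05; adjusted p = 0.816 with an estimated correlation), with Creld2 the 1 of 22 that passed over all genes and 8 lower when adjusted over the list alone. Macrophage genes fell as a list (median log2 -0.40, 29 genes, adjusted p = 0.00268; adjusted p = 0.816 with an estimated correlation), and so did monocyte and neutrophil genes (-2.03, or -1.12 with the 3 genes that had 0 reads in a group at their bound; adjusted p = 0.0217; adjusted p = 0.816 with an estimated correlation). Neither of these 2 lists passed without NT 1 (adjusted p = 0.185 and 0.215). The salivary acinar genes (adjusted p = 0.441), granular convoluted tubule genes (0.351) and Hedgehog target genes (0.220) did not pass. The NT samples differed in sublingual gland genes, whose CPM summed to 31458 in NT 2 and 3 and to 3.59 in NT 1; in this list, with a median log2 of -12.39, Gal3st3 rose (1.15 ± 0.19) and 5 of 6 genes did not pass.

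Of all genes tested, 51.2% had no overlap between the groups' samples, against 33.3% by chance with 2 samples against 2. The number of genes changed was 538 without NT 1, 21 without NT 2 and 3, 16 without IR 1 and 2, and 9 without IR 3; Eda2r, Trp53inp1, Phlda3, Ccng1 and Tmem44 passed without each of IR 3, IR 1 and 2 and NT 2 and 3. The number of lists passing camera was 17 without IR 1 and 2. The number of genes was 311 without IR+GFP 3 and IR+Gli1 3, which carry more reads with several alignments and enter this comparison through the shared spread.

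**Figure D2:**
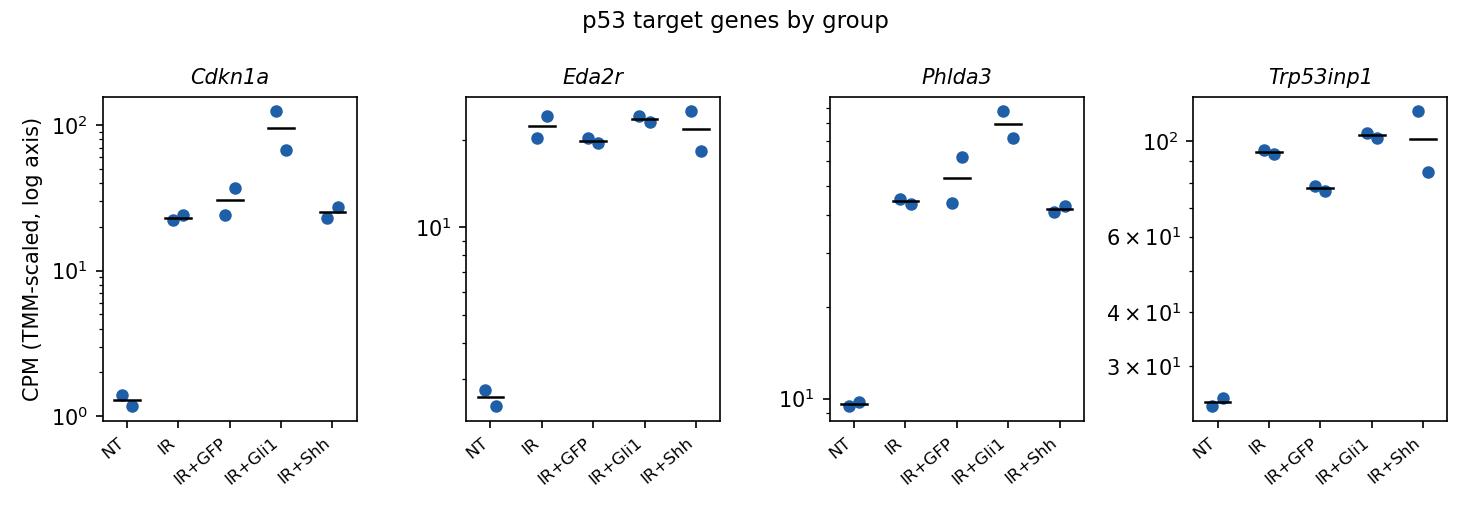
Levels of 4 p53 target genes in CPM (vertical log axis) in the 10 samples, by group (horizontal axis), with points for samples and lines for group means. Both NT samples lie below all 8 irradiated samples; for Cdkn1a the means are 1.28 CPM in NT and 23.2 CPM in IR.

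IR+GFP against IR asked what the gene transfer itself changed in irradiated glands. With edgeR, 0 of 14300 genes changed; 298 genes had an unadjusted p under 0.05, limma-voom found 0 and DESeq2 found 8. The genes with the smallest p were Plekhm3 (log2 -0.82 ± 0.19), Ccnb2 (-1.89 ± 0.44) and Xlr3a (1.90 ± 0.44), none of which passed (adjusted p = 1.00 each). Of the 34 gene lists, 11 passed camera, and none did with an estimated correlation (lowest adjusted p = 0.616) or with fry. Among them, cell cycle genes had a median log2 of -0.44 (31 genes, adjusted p = 1.67e-05) and interferon response genes a median log2 of 0.21 (32 genes, adjusted p = 0.0016). Sublingual gland genes, with 164 CPM in all in IR+GFP 1 and 2 and 5.99 CPM in IR+GFP 3, had a median log2 of 5.55 (6 genes, adjusted p = 0.0362). With an estimated correlation the adjusted p of these 3 lists was 0.702, 0.855 and 0.855. The other lists passing camera had medians above 0 for immediate early and heat shock (log2 0.22), antigen presentation (0.23), T and NK cell (0.36, or 0.31 with the 1 gene at 0 reads at its bound) and circadian clock genes (0.16), and below 0 for skeletal muscle (-0.79), B and plasma cell (-1.68), fibroblast and matrix (-0.19) and neurotrophic genes (-0.62). Without IR+GFP 1 and 2, 1 gene passed, H2-Q6 (log2 2.47), chosen after its values were seen. The number of lists passing camera was 6 without IR+GFP 1 and 2, and 6 without IR 3. Without IR+GFP 1 and 2 the sublingual (adjusted p = 0.857, downward), cell cycle (0.331), immediate early (0.129), circadian (0.902), B and plasma cell (0.583), fibroblast (0.993) and neurotrophic lists (0.848) did not pass. Without IR 3 the sublingual (0.175), interferon (0.549), antigen presentation (0.267), T and NK cell (0.0653), B and plasma cell (0.337), fibroblast (0.889) and neurotrophic lists (0.959, upward) did not, and without IR 1 and 2 the sublingual (0.124) and circadian lists (0.139) did not. The interferon (adjusted p = 0.535), antigen presentation (0.359, downward) and T and NK cell lists (0.524) did not pass without IR+GFP 3, nor without IR+GFP 3 and IR+Gli1 3 together.

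IR+Gli1 against IR+GFP asked what differed between the group labelled IR+Gli1 and the vector control. Gli1 itself did not pass, and its direction turned with the scaling (log2 -0.16 ± 0.37, adjusted p = 0.832; log2 0.63, adjusted p = 0.201 with total-count scaling). Genes induced by interferon and genes of several immune cell types were higher, and genes of the granular convoluted tubules, the duct segment of the male mouse gland that stores growth factors and kallikreins, were lower. All 32 measured interferon response genes rose, also when adjusted over the list alone, with a median log2 of 3.99. Stat2, a transcription factor of interferon signalling, was 3.77-fold higher, at 79.2 ± 17.3 CPM in IR+Gli1 and 21.1 ± 0.378 CPM in IR+GFP (SD, n = 2; log2 1.91 ± 0.16, adjusted p = 0.0013). Klk1b9, a tissue kallikrein, was 5.59-fold lower (log2 -2.48 ± 0.37, n = 2 per group, adjusted p = 0.00545). In total 1993 genes changed, 1177 upward and 816 downward; with total-count scaling 9660 were higher and 89 lower.

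Within the interferon list, the RNA sensors Ddx58 (log2 1.83 ± 0.17) and Ifih1 (1.67 ± 0.16) rose beside Stat2. Of 17 antigen presentation genes, 14 rose, 0 fell and 3 did not pass (16 rose when adjusted over the list alone; median log2 1.96). B2m, the light chain of class I molecules, rose 6.57-fold (log2 2.72 ± 0.27), H2-K1 6.26-fold (2.65 ± 0.30), H2-D1 4.67-fold (2.22 ± 0.25) and Tapbp 3.90-fold (1.96 ± 0.22). Of 21 inflammatory cytokine and NF-kB genes, 13 rose and 8 did not pass (15 rose when adjusted over the list alone; median log2 1.58), among them Nfkbia (1.58 ± 0.12), the adhesion molecule Vcam1 (2.73 ± 0.26) and Relb (1.64 ± 0.23). The preset correlation gave adjusted p = 1.86e-66 for the interferon list, 6.72e-27 for antigen presentation and 2.69e-14 for NF-kB. All 3 lists had adjusted p = 0.137 with an estimated correlation and adjusted p = 0.0113 with fry.

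Lists of 3 of the 5 immune cell types rose as well, while dendritic cell genes (median log2 -0.27, 8 genes, adjusted p = 0.266) and B and plasma cell genes (0.33, 5 genes, adjusted p = 0.467) did not pass. Of 29 macrophage genes, 16 rose and 13 did not pass (17 rose when adjusted over the list alone; median log2 1.10, adjusted p = 2.75e-14; adjusted p = 0.137 with an estimated correlation). Siglec1, a sialic acid receptor of macrophages, rose 5.24-fold (log2 2.39 ± 0.22), Ms4a7 4.38-fold (2.13 ± 0.26), and the complement genes C1qb 3.06-fold (1.61 ± 0.16) and C1qc 2.84-fold (1.51 ± 0.14). Of 16 macrophage growth factors and chemokines, 11 rose, 1 fell and 4 did not pass (12 and 1 when adjusted over the list alone; median log2 1.90; list adjusted p = 0.137 with an estimated correlation). Cx3cl1 (1.17 ± 0.15), Csf1 (1.00 ± 0.16), Il34 (0.77 ± 0.13) and Ccl12 (4.19 ± 0.66) rose. The member that fell was the vascular growth factor Vegfa (-1.30 ± 0.23), chosen after its values were seen. Of 10 monocyte and neutrophil genes, 6 rose and 4 did not pass (8 when adjusted over the list alone), with a median log2 of 5.64, or 4.89 with the 2 genes at 0 reads set to their bound (list adjusted p = 0.219 with an estimated correlation). Plac8 rose 34.2-fold (log2 5.09 ± 0.71). Of 15 T and NK cell genes, 8 rose and 7 did not pass (14 when adjusted over the list alone; median log2 2.53; list adjusted p = 0.233 with an estimated correlation); the cytotoxic granule genes Gzmb (4.74 ± 0.68), Gzma (4.67 ± 0.68) and Prf1 (3.13 ± 0.50) rose.

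The largest rises were in genes with almost no reads in IR+GFP. The acute phase gene Saa3 was at least 636-fold higher, Slpi at least 162-fold, Ubd at least 97.6-fold, Chil3 at least 81.3-fold, Clec4e at least 59.0-fold, Treml2 at least 38.7-fold and Sirpb1a at least 35.4-fold, against a floor of 3 reads over the IR+GFP group. Ltf, which encodes lactoferrin, had 3 reads in IR+GFP after pairs were averaged, and the ratio was 1421 (counting interval 486 to 6892). Of 22 senescence and SASP genes (secreted factors of senescent cells), 8 rose and 14 did not pass (9 rose when adjusted over the list alone). Those that rose included Mmp3 (log2 2.61 ± 0.23), Timp1 (4.05 ± 0.47), Tnf (4.61 ± 0.74) and Ccl2 (6.30 ± 0.90). The camera adjusted p of this list was 1.11e-05, and adjusted p = 0.219 with an estimated correlation. The list did not pass with total-count scaling. Of 31 cell cycle genes, 9 rose and 22 did not pass (13 when adjusted over the list alone; median log2 0.86, adjusted p = 8.46e-07; adjusted p = 0.328 with an estimated correlation). Examples are the replication genes Mcm6 (1.30 ± 0.21) and Mcm5 (1.82 ± 0.33) and the topoisomerase Top2a (2.24 ± 0.38). The control itself was measured low in cell cycle genes, with a median log2 of -0.44 in IR+GFP against IR. Mean Top2a was 2.53 CPM in NT, 1.57 in IR, 0.689 in IR+GFP and 3.21 in IR+Gli1.

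Of 19 granular convoluted tubule genes, 16 fell, 1 rose and 2 did not pass, with the same counts when adjusted over the list alone (median log2 -1.76, adjusted p = 1.53e-12; adjusted p = 0.233 with an estimated correlation). Beside Klk1b9, the kallikreins Klk1b21 (-1.93 ± 0.37) and Klk1b11 (-1.46 ± 0.27) and the secretory gene Crisp3 (-1.29 ± 0.23) fell. Egf (-2.06 ± 0.44), a growth factor made in these ducts, fell, and Tgfa rose (0.69 ± 0.19); both were chosen after their values were seen. The kallikrein genes are close copies, and reads aligned to several places were left out of the gene counts; such reads made up 8.22% of IR+GFP 3 and 7.53% of IR+Gli1 3, against 2.89% to 4.79% in the other libraries. The largest falls among all genes included Syt16 (-3.03 ± 0.58), Faim2 (-2.65 ± 0.51), Gnat2 (-2.60 ± 0.38), Crisp1 (-2.59 ± 0.42), Klk1b27 (-2.56 ± 0.49), Prss12 (-2.56 ± 0.47) and Klk1b8 (-2.47 ± 0.48).

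Secretory and metabolic groups changed as well. Of 22 endoplasmic reticulum stress and secretory genes, 6 fell, 1 rose and 15 did not pass (12 lower and 1 higher when adjusted over the list alone). Their median log2 was -0.60, and 0.15 with total-count scaling, which moved the median of all genes by 0.79 (adjusted p = 1.34e-06; adjusted p = 0.287 with an estimated correlation). Dnajb9 (-1.14 ± 0.12), Herpud1 (-1.16 ± 0.22) and Sec61b (-0.80 ± 0.14) fell, and Ddit3, chosen after its values were seen, rose (0.75 ± 0.16). Of 12 genes of the mitochondrial genome, 9 fell and 3 did not pass (12 lower when adjusted over the list alone; median log2 -0.84, and -0.084 with total-count scaling; adjusted p = 6.86e-06; adjusted p = 0.355 with an estimated correlation); mt-Co3 had -0.86 ± 0.17, and mt-Nd3 (-0.62 ± 0.14) and mt-Atp6 (-0.73 ± 0.18) had the opposite sign with total-count scaling. Circadian clock genes fell as a list (5 of 17 lower, 9 lower and 1 higher when adjusted over the list alone; median log2 -0.42, and 0.39 with total-count scaling; adjusted p = 0.0105, and adjusted p = 0.233 with an estimated correlation). Salivary acinar genes (median log2 -0.37, and 0.40 with total-count scaling; adjusted p = 0.0390) included Bhlha15 (-0.82 ± 0.21), a regulator of secretory cell maturation, which fell, and the chloride channel Ano1 (0.66 ± 0.15), which rose; the adjusted p of this list was 0.432 with an estimated correlation. Duct and ionocyte genes rose as a list (median log2 0.28, adjusted p = 0.0147; adjusted p = 0.355 with an estimated correlation), with Wfdc2 (2.33 ± 0.37) and the iodide transporter Slc5a5 (1.09 ± 0.21). Hedgehog target genes did not pass (median log2 0.069, 9 genes, adjusted p = 0.266), with 1 member higher, Ccnd2 (0.92 ± 0.19), and the p53 targets did not pass (adjusted p = 0.0569), although Psrc1 (2.05 ± 0.38) and Cdkn1a (1.66 ± 0.30) rose further. Lymph node stroma (median log2 2.07, adjusted p = 0.0105), basal and progenitor (0.48, adjusted p = 0.0214) and endothelial genes (0.55, adjusted p = 0.0299) also rose as lists, and sublingual gland genes (-7.00, or -6.33 with the 1 gene at 0 reads at its bound; adjusted p = 0.0214) and erythroid genes (-1.30, adjusted p = 0.0390) fell; with an estimated correlation the adjusted p of these 5 lists was 0.190, 0.262, 0.548, 0.432 and 0.432. The sublingual genes summed to 164 CPM in IR+GFP 1 and 2 and to 5.99 CPM in IR+GFP 3; their median log2 was -6.77 for IR+Gli1 1 and 2 against IR+GFP 1 and 2 and -0.70 for IR+Gli1 3 against IR+GFP 3, and the list did not pass without IR+GFP 1 and 2 (adjusted p = 0.147) or without IR+Gli1 3 (0.112). Without IR+GFP 1 and 2, the endothelial, basal and progenitor, erythroid, salivary acinar and circadian lists did not pass either. The duct, endothelial and erythroid lists did not pass without IR+Gli1 3, nor the acinar, endothelial and erythroid lists without IR+Gli1 1 and 2. The acinar median log2 was -0.58 for IR+Gli1 1 and 2 against IR+GFP 1 and 2 and -0.18 for IR+Gli1 3 against IR+GFP 3. The endothelial list passed in 10 of 16 alternative settings and the erythroid list in 8 of 16. With total-count scaling the endothelial, lymph node stroma and basal and progenitor lists did not pass.

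Of all genes tested, 56.1% had no overlap between the samples of the groups, against 33.3% by chance. The number of genes changed was 91 without IR+GFP 1 and 2, 1013 without IR+GFP 3, 610 without IR+Gli1 1 and 2, and 2987 without IR+Gli1 3, and it was 2535 without IR+GFP 3 and IR+Gli1 3 together. A fit of the 4 samples of these groups alone called 1 gene, Wfdc18 (log2 4.23, chosen after its values were seen). With the difference of the pair IR+GFP 3 and IR+Gli1 3 from the other samples as a term, it called 957 genes, 845 of them among the 1993. In that fit 20 lists passed. The term was chosen after the data were seen. With the group means and the term taken from 4 samples, the calls rest largely on the spread shared across genes. The median log2 of the interferon list was 4.78 for IR+Gli1 1 and 2 against IR+GFP 1 and 2 and 3.02 for IR+Gli1 3 against IR+GFP 3, and that of the granular tubule list -2.48 and -1.24.

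**Figure D3:**
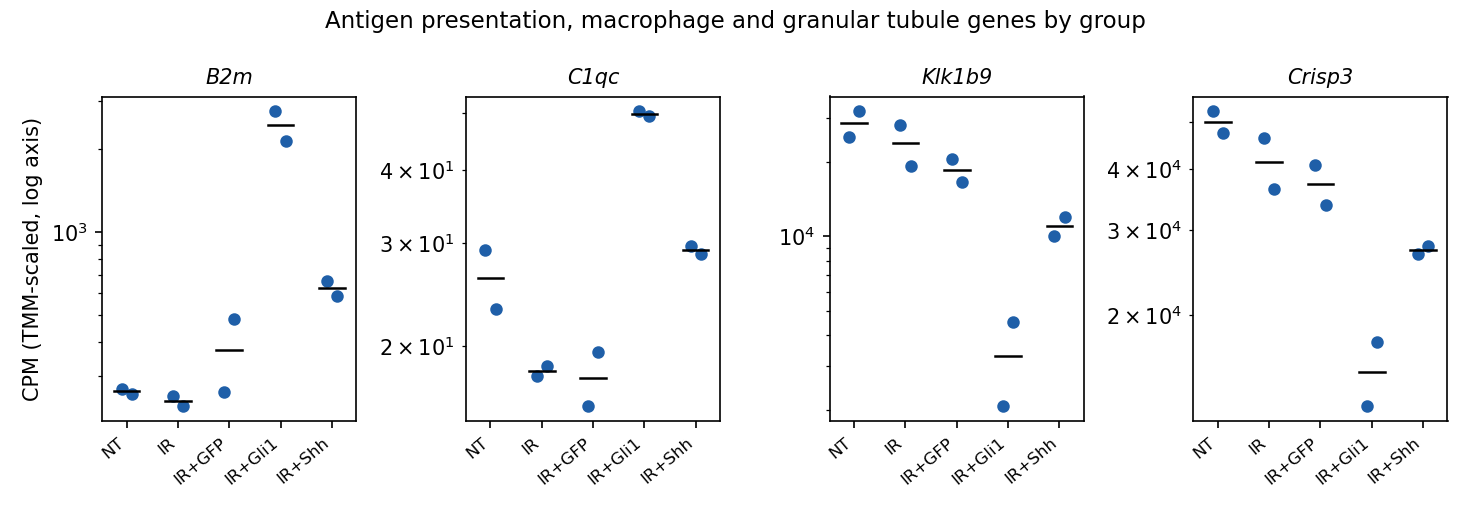
Levels of 4 genes in CPM (vertical log axis) in the 10 samples, by group (horizontal axis), with points for samples and lines for group means. B2m and C1qc are higher in both IR+Gli1 samples than in both IR+GFP samples (B2m means 2452 and 373 CPM), and Klk1b9 and Crisp3 are lower.

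IR+Shh against IR+GFP asked what differed between the group labelled IR+Shh and the vector control. Gli1 was measured 5.16-fold higher (log2 2.37 ± 0.35, n = 2 per group, both IR+Shh samples above both IR+GFP samples), but it did not pass over all genes (adjusted p = 0.330). With edgeR, 0 of 14300 genes changed; 872 genes had an unadjusted p under 0.05, limma-voom found 0 and DESeq2 found 34. Pde4b, a phosphodiesterase (log2 0.91 ± 0.11, adjusted p = 0.175), and the nuclear body gene Sp100 (0.74 ± 0.11, adjusted p = 0.330) were the other genes with the smallest p. Of 9 Hedgehog target genes 6 were measured higher and none passed (median log2 0.22, mean 0.69, list adjusted p = 0.0787). The receptor gene Ptch1 had a log2 fold change of 0.48 ± 0.20.

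Among the lists, 12 of 34 passed camera and none did with an estimated correlation or with fry. Interferon response genes had a median log2 of 0.82 (31 of 32 positive, adjusted p = 3.95e-15), macrophage genes 0.65 (29 genes, 6 higher when adjusted over the list alone, adjusted p = 1.04e-14), cell cycle genes 0.72 (30 of 31 positive, 2 higher when adjusted over the list alone, adjusted p = 3.20e-10) and T and NK cell genes 0.97 (15 genes, adjusted p = 3.81e-06). Granular convoluted tubule genes had a median log2 of -0.66 (19 genes, adjusted p = 1.98e-06). With an estimated correlation the adjusted p was 0.480 for the interferon, cell cycle and T and NK cell lists, 0.468 for macrophage genes and 0.549 for tubule genes. Members with the smallest p, none passing, were C1qc (0.73 ± 0.14), C1qb (0.81 ± 0.16), Ccnb2 (2.25 ± 0.43), Top2a (1.84 ± 0.38), Ifih1 (0.56 ± 0.16) and Klk1b8 (-1.13 ± 0.46). For cell cycle genes the control itself was measured low, with a median log2 of -0.44 in IR+GFP against IR. Mean Top2a was 2.53 CPM in NT, 1.57 in IR, 0.689 in IR+GFP and 2.47 in IR+Shh. Mean Mki67 was 3.53, 3.17, 2.31 and 4.53 CPM in the same groups. Sublingual gland genes, of which IR+GFP 1 and 2 carried 164 CPM, had a median log2 of -6.08, or -5.11 with the 1 gene at 0 reads at its bound (adjusted p = 0.000666; adjusted p = 0.480 with an estimated correlation, and adjusted p = 0.531 without IR+GFP 1 and 2). Antigen presentation genes (median log2 0.32), macrophage growth factors and chemokines (0.35), fibroblast and matrix (0.25), NF-kB (0.24) and basal and progenitor genes (0.25) passed upward and erythroid genes (-0.93) downward, with adjusted p = 0.480 to 0.549 with an estimated correlation. With a term for IR+GFP 3 and IR+Gli1 3, the macrophage growth factor, NF-kB and basal and progenitor lists did not pass. The NF-kB list passed in 7 of 15 alternative settings and the basal and progenitor list in 8 of 15. Without IR+GFP 3 and IR+Gli1 3, Lyz2 (log2 1.43) and H2-Q6 (1.65) passed, and with the difference of these libraries as a term Igfbp4 (1.61) and C1qa (1.05) did; Lyz2, H2-Q6 and C1qa were chosen after their values were seen. The number of lists passing camera was 6 without IR+GFP 1 and 2, 20 without IR+GFP 3 and 21 without IR+GFP 3 and IR+Gli1 3. Without IR+GFP 1 and 2, the T and NK cell (adjusted p = 0.168), antigen presentation (0.954), NF-kB (0.531), fibroblast and matrix (0.573), basal and progenitor (0.576) and erythroid lists (0.240) did not pass.

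**Figure D4:**
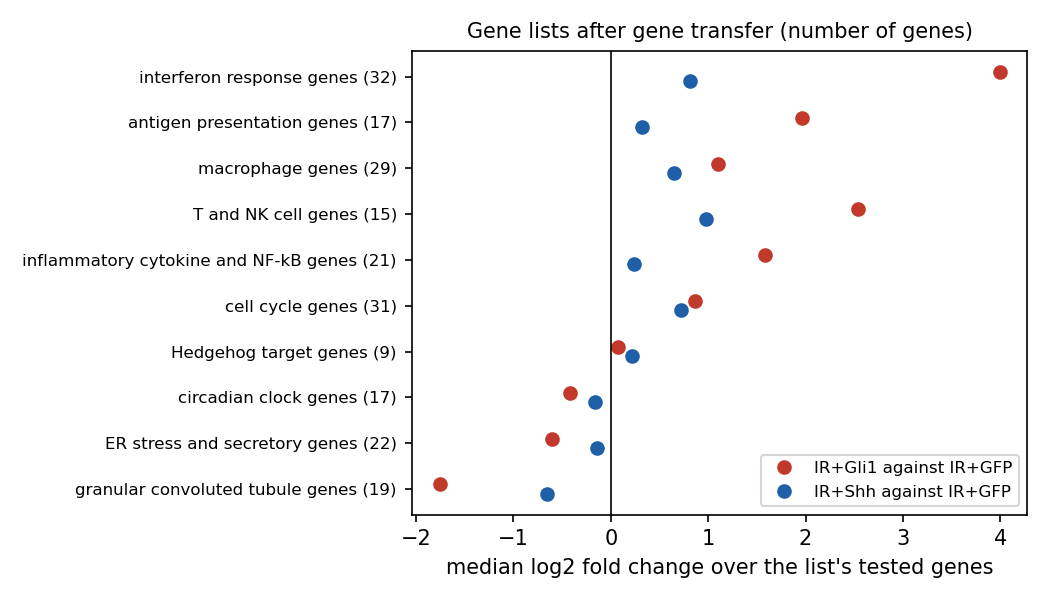
Median log2 fold change over the tested genes of 10 gene lists (horizontal axis; list and number of genes on the vertical axis) in IR+Gli1 and IR+Shh against IR+GFP. Points are list medians; the interferon list lies at 3.99 and 0.82 and the granular convoluted tubule list at -1.76 and -0.66, and the medians of the circadian clock and endoplasmic reticulum lists in IR+Gli1 and of the endoplasmic reticulum list in IR+Shh change sign with total-count scaling.

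IR+Shh against IR+Gli1 asked where the Hedgehog transfers differed from each other. Gli1 was 5.77-fold higher in IR+Shh (log2 2.53 ± 0.34, n = 2 per group, adjusted p = 0.00879), and interferon and immune genes were lower. In total 1109 genes changed, 395 higher and 714 lower in IR+Shh; with total-count scaling 84 were higher and 8008 lower. Of 32 interferon response genes, 31 were lower and 1 did not pass (32 lower when adjusted over the list alone; median log2 -3.35, adjusted p = 3.42e-58; adjusted p = 0.245 with an estimated correlation). Stat2 had a log2 fold change of -1.47 ± 0.16 and Gbp7 of -2.33 ± 0.28.

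Of 17 antigen presentation genes 12 were lower (14 when adjusted over the list alone; median log2 -1.82), including Tapbp (-2.13 ± 0.22) and B2m (-1.97 ± 0.26), and of 21 NF-kB genes 10 were lower (13 when adjusted over the list alone). Of 29 macrophage genes 11 were lower and 1, the mannose receptor Mrc1 (1.02 ± 0.21, chosen after its values were seen), was higher; 15 and 3 passed when adjusted over the list alone. The adjusted p with an estimated correlation was 0.245 for antigen presentation and NF-kB and 0.333 for macrophage genes. The matrix protease gene Mmp3 (-3.41 ± 0.24), Saa3 (-7.20 ± 0.58) and Slfn4 (-6.71 ± 1.04) were lower. Slpi had 1 read in IR+Shh after pairs were averaged, with a ratio of 691 (counting interval 124 to 27299.7). Granular convoluted tubule genes were higher as a list (median log2 1.12, adjusted p = 1.25e-07; adjusted p = 0.367 with an estimated correlation), with 2 of 19 passing over all genes, Klk1b9 (1.73 ± 0.36) and Klk1b11 (1.15 ± 0.27), and 17 higher and 1 lower when adjusted over the list alone. The p53 targets were lower as a list (median log2 -0.28, adjusted p = 0.000646; adjusted p = 0.367 with an estimated correlation), with 6 of 28 lower, among them Cdkn1a (-1.93 ± 0.31) and Phlda3 (-0.93 ± 0.16). Monocyte and neutrophil genes (6 of 10 lower; median log2 -4.75, or -4.52 with the 1 gene at 0 reads at its bound), macrophage growth factors and chemokines (9 of 16 lower), senescence and SASP genes (7 of 22) and T and NK cell genes (3 of 15) were lower as lists, as were duct and ionocyte (4 of 19), lymph node stroma (1 of 4) and immediate early and heat shock genes (3 of 17). Mitochondrial genome genes were higher (3 of 12). Fibroblast and matrix (median log2 0.51), endoplasmic reticulum stress (0.49), circadian clock (0.34), salivary acinar (0.29) and myoepithelial genes (0.24) were higher as lists, with medians of -0.12, -0.11, -0.30, -0.33 and -0.39 under total-count scaling, which moved the median of all genes to -0.67. With an estimated correlation the adjusted p of these lists was 0.245 to 0.608. Endothelial genes (0 of 18 lower) passed in the fit but in only 4 of 15 alternative settings, myoepithelial genes in 6, immediate early genes in 8, and lymph node stroma genes in 9 of 14. Without IR+Gli1 1 and 2 the acinar list did not pass (adjusted p = 0.263), and without IR+Gli1 3 the duct list did not (0.111). Hedgehog target genes did not pass (adjusted p = 0.953).

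Beside Gli1, the largest values on the higher side in IR+Shh were those of Adamtsl2 (log2 3.46 ± 0.43), the Notch target Heyl (2.52 ± 0.43), Tmem178b (2.28 ± 0.35), the secretoglobin gene Scgb2b26 (2.22 ± 0.39), Hist1h2be (2.16 ± 0.44), Gfra2 (2.11 ± 0.48), a receptor for neurturin, and Crispld1 (2.08 ± 0.42). Of all genes tested, 58.5% had no overlap between the groups' samples, against 33.3% by chance. The number of genes changed was 0 without IR+Shh 2, 4 without IR+Shh 1 and 3 (F13a1, Saa3, Mmp3 and Apof, of which F13a1 and Apof were chosen after their values were seen), 221 without IR+Gli1 1 and 2, 2286 without IR+Gli1 3 and 2392 without IR+GFP 3 and IR+Gli1 3. A fit of the 4 samples of these groups alone called 9 genes.

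Genes changed by irradiation were then followed in the gene transfer groups. The sets were defined by IR against NT, but the gene transfer samples were in the same fit. They entered it through the shared spread, the filter and the scaling, so the sets are not fully independent of them. The 74 genes that rose in IR had a median log2 of 0.047 in IR+Gli1 against IR+GFP (adjusted p = 0.947) and -0.012 in IR+Shh (adjusted p = 0.809). The 23 that fell had medians of -0.084 (adjusted p = 0.809) and -0.079 (adjusted p = 0.947). In IR+Gli1, 8 of the 74 rose further where 6.09 would by overlap at random (two-sided Fisher's exact p = 0.394), among them Cdkn1a, Psrc1, Bax, Phlda3 and Pik3ip1, and 3 fell (Dnah11, Gal3st3 and Bcas3). Of the 23, Tubb5, Psmd14 and Ran rose and Tmem56, Cdc25a and Ostc fell. Sets of the 200 genes of smallest p in each direction were also tested, most of which had not passed in IR against NT. The downward 200 had a median log2 of -0.056 in IR+Gli1 and -0.057 in IR+Shh. Their camera p, not adjusted, was 0.0193 and 0.00643. The median of the lowered set in IR+Shh was 0.042 without IR+GFP 1 and 2, -0.0060 without IR+Shh 1 and 3 and -0.026 without IR+Shh 2; that of the raised set in IR+Gli1 was 0.0089 without IR+Gli1 1 and 2, 0.025 without IR+GFP 1 and 2 and -0.016 without IR+Gli1 3.

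The log2 fold changes of IR+Gli1 and IR+Shh, both against IR+GFP, correlated across the 14300 genes with r = 0.428, where genes are not independent replicates. Because both share the IR+GFP samples, unchanged groups simulated against the same controls gave a mean r of 0.530 and at most 0.586 in 100 simulations. The observed r lay below these. The simulated groups had no response of their own, while 1993 genes changed in IR+Gli1 against IR+GFP. A response in 1 group alone lowers r, so the simulated r is no reference for the observed r. The covariance was 0.154, above the simulated mean of 0.0964 and the simulated maximum of 0.121, and 65.2% of genes had the same sign, against 67.6% in the simulations. The shared controls and a shared response were not split with 2 control samples. The r was 0.131 without IR+Gli1 1 and 2 and 0.612 without IR+GFP 3 and IR+Gli1 3.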

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

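All tests in this part were chosen after the result was seen, except that of the pan-leukocyte genes, whose outcome was predicted before it was run. Reads aligned to several places, which are outside the gene counts, made up 8.22% of the reads of IR+GFP 3 and 7.53% of those of IR+Gli1 3. In the 3 untreated libraries they made up 3.18% to 4.61%, and in the other 10 libraries 2.89% to 4.79%. IR+GFP 3 and IR+Gli1 3 stood out because they lay above 6.04%, the highest untreated value plus the range of the untreated values.

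IR+GFP 3 and IR+Gli1 3 also stood apart in gene counts, with 329 genes higher and 85 lower than in the other samples of their own groups. The term was fitted beside 1 mean per group, so the other groups do not enter these differences. Of the 85 lower genes, 40 were pseudogenes (47.1%, against 2.31% of all genes tested; Fisher's exact p = 3.54e-43), as a difference in how reads with several alignments were counted would give; this remains a candidate explanation for these. Of the 329 higher genes 22 were pseudogenes (6.69%), and the higher side, with Gm42418 (log2 18.96), Gm23935 (17.73), Gm26880 (14.17) and Lars2 (7.57), was not tested and stays unexplained. Another tissue taken with these glands cannot be told apart. The sublingual list had the largest median log2 difference in size, 4.75 (-4.75, adipose list 4.54), but no other-tissue list passed camera (adjusted p = 0.681 for both). Sublingual genes summed to 164 CPM in IR+GFP 1 and 2 and to 5.99 CPM in IR+GFP 3. They summed to 4.23 CPM in IR+Gli1 1 and 2 and to 3.56 CPM in IR+Gli1 3. The reads behind the sublingual difference were thus mainly those of IR+GFP 1 and 2. No biological explanation was tested, because IR+GFP 3 and IR+Gli1 3 belong to different groups.

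Per total gene reads, sublingual gland genes summed to 31458 CPM in NT 2 and 3, against 3.59 CPM in NT 1. Of the 6 genes of the list, 5 were at least 4 times higher in NT 2 and 3, which repeats the observation, so whether sublingual tissue was taken with the gland cannot be told from it; the most abundant were Dcpp3 (14576 CPM) and Dcpp2 (11861 CPM). IR+GFP 1 and 2 held 164 CPM of these genes. The ratio of Dcpp1 to Muc19 reads there was 0.826 (0.724 to 0.942), against 2.92 in NT 2 and 3. Carry-over from those NT libraries as the only source would keep this ratio, so the Muc19 reads argue against it. Among the Dcpp genes the proportions were similar. Dcpp1, Dcpp2 and Dcpp3 had 15.4, 55.3 and 69.5 CPM in IR+GFP 1 and 2, and 3641, 11861 and 14576 CPM in NT 2 and 3. Carry-over of part of the reads thus stays open. No biological explanation was tested.

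The interferon genes were higher in IR+Gli1 than in IR+GFP, with a median log2 of 3.99. With total-count scaling the median was 4.84, but that scaling raises all genes in this comparison, so this value could not decide on scaling. A change of scaling moves all genes alike. The list lay above the median of all genes with either scaling (0.0054 with TMM and 0.79 with total counts). The difference of the libraries that stand apart does not account for the rise, since the lower of the medians within like libraries was 3.02. A larger share of all leukocytes alike may raise such genes, but the 12 pan-leukocyte genes had a median of 2.302 (quartiles 2.16 to 2.53), below the interferon quartiles of 3.48 to 4.99; 11 of the 12 rose, and Lcp1, the most abundant at 184 CPM in IR+GFP, did not (log2 -0.16). Monocyte and neutrophil genes had a median of 5.64, or 4.89 with the 2 genes at 0 reads at their bound; it was 5.70 in IR+Gli1 1 and 2 and 2.49 in IR+Gli1 3, each against the like IR+GFP library, where the interferon medians were 4.78 and 3.02. An influx of these cells, their activation, an effect of the vector and an effect of Gli1 itself stay open as untested hypotheses.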

How the results depend on the processing

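Combining libraries was decided after the data were seen, and the planned fit of 15 separate libraries was then set beside it. The tests with the term or omission for IR+GFP 3 and IR+Gli1 3, the deeper library, protein-coding genes, total-count scaling and IR with IR+GFP as control were chosen after the result was seen. Counts of changed genes were within 1.5 times the reported ones, in all 5 comparisons, with DESeq2 size factors, upper-quartile scaling, the filter at 1 CPM, the deeper library of each pair and protein-coding genes alone. Where values are given below, the cause was not tested unless stated.

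Without a low-count filter, 1242 genes changed in IR against NT, 210 in IR+GFP against IR, 435 in IR+Shh against IR+GFP and 2639 in IR+Shh against IR+Gli1. With 15 separate libraries the counts were 4154, 5 (Nolc1, Fbxl20, Ccnb2, D630003M21Rik and Plekhm3, chosen after their values were seen), 6518 (IR+Gli1 against IR+GFP), 538 and 6065, and with the replicate block 4048, 6495, 433 and 6092 in the comparisons other than IR+GFP against IR; the near-identical libraries enter these fits as if independent. With the term for IR+GFP 3 and IR+Gli1 3, 182 genes changed in IR against NT and 2 in IR+Shh against IR+GFP. Without these libraries 311, 2 and, in IR+Shh against IR+Gli1, 2392 changed, and 21 lists passed in IR+Shh against IR+GFP. DESeq2 called 479 genes in IR against NT, 8 in IR+GFP against IR and 34 in IR+Shh against IR+GFP, and limma-voom 55 in IR against NT. Fits of the compared groups alone called 1 gene in IR+Gli1 against IR+GFP (957 with the term), 24 in IR+Shh against IR+GFP and 9 in IR+Shh against IR+Gli1. IR with IR+GFP as control gave 3273 genes for IR+Gli1.

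Total-count scaling moved the median log2 of all genes to 0.79 in IR+Gli1 against IR+GFP, with 9749 genes called, and to -0.67 in IR+Shh against IR+Gli1, with 8092 called. The shift follows from its construction, since the 10 most abundant genes held 24.5% to 38.1% of reads in IR+Gli1 and 45.4% to 53.2% elsewhere. It reversed Slc12a2 (0.036), Postn (0.068), Edem1 (0.044), Tef (0.11), Nr1d2 (0.26), Cry2 (0.40), mt-Nd3 (0.18) and mt-Atp6 (0.051) in the first, and Atm (-0.014), Sparc (-0.12), Sec61b (-0.014), Tef (-0.015) and Nr1d2 (-0.088) in the second.

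With an estimated correlation 1 list passed in IR against NT and 0 in each other comparison; fry gave 2 lists in IR against NT, 0 in IR+GFP against IR and in IR+Shh against IR+GFP, and 11 in IR+Shh against IR+Gli1. The filter at 1 CPM left 7 lists in IR+GFP against IR. With sets of 200 genes the irradiation-raised medians were -0.017 in IR+Gli1 and -0.0038 in IR+Shh, and the lowered ones -0.056 and -0.057. The lowered sets had a camera p, not adjusted, of 0.0193 and 0.00643. The r between IR+Gli1 and IR+Shh was 0.612 without IR+GFP 3 and IR+Gli1 3.

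Leaving out each sample in turn assumes that a lone sample varies like the other groups. In the order of the report, the counts of genes were 9 to 538, 0 to 1, 91 to 2987, 0 to 0 and 0 to 2286, and those of lists 5 to 17, 6 to 13, 16 to 21, 6 to 20 and 16 to 22. Irradiation-raised medians were -0.016 to 0.035 in IR+Gli1 and -0.048 to 0.011 in IR+Shh, lowered ones -0.096 to -0.044 and -0.089 to 0.042, and r was 0.131 to 0.625. The values of named genes that passed were also followed over all alternative fits pooled, most of which leave out no sample. Direction and threshold were kept by 327 of 396 values in IR against NT and 1686 of 2013 in IR+Gli1 against IR+GFP. In IR+Shh against IR+Gli1 they were kept by 1194 of 1544. Direction alone was kept by 69, 319 and 345 values. These pooled counts do not measure how stable the genes were to leaving out a sample.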

Other observations

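The 10 most abundant genes held 24.5% of gene reads in IR+Gli1 1 and 2 and 38.1% in IR+Gli1 3, against 45.4% to 53.2% in the other 12 libraries. The TMM factors of the IR+Gli1 samples were 1.72 and 1.31, and those of the other 8 samples 0.865 to 0.994. Mucl2 alone held 12.3% of gene reads in IR+Gli1 1 and 17.9% in IR+Gli1 3, against 16.6% to 32.6% in the libraries of the other groups.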
